A study of Homo sapiens with 6 samples.

How the data were processed

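RNA was sequenced from SW480 cells, an established line of human colon adenocarcinoma cells, in 6 libraries. The labels put 3 libraries in the control group LV-NC and 3 in the group MUCP1-FLAG, labelled as overexpressing MUCP1. Cells of both groups were kept in L-15 medium with fetal bovine serum, RNA was extracted with Trizol, and libraries were made with an mRNA kit, per the labels' protocols. The labels call the libraries of a group biological replicates and give no day, passage, clone or batch. The p-values of single genes below therefore measure the spread between these libraries. What else differed between the 2 groups of cultures was not analysed here.

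The deposited table held 20289 genes by Ensembl identifier, of which 583 had no symbol. Of these genes 19783 are protein-coding in GENCODE 29, 303 are immunoglobulin or T cell receptor segments, 85 are of other types and 118 are absent from that release. Gene symbols were taken from the table and current symbols from a gene name table, which matched 20257 of the identifiers. For each library the authors deposited whole-number read counts per gene and FPKM values, that is, counts scaled for gene length and library size. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the build GRCh38, without versions or the role of each tool. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes cannot be assigned with certainty. The table also held the authors' own comparison, with a p-value, an adjusted p-value and a log2 fold change per gene deposited by the authors. Recalculation showed that this log2 fold change was the log2 ratio of the mean deposited FPKM values of the 2 groups, with a floor of 0.001 FPKM. The test behind the deposited p-values is not given in the sources used here.

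Counts and FPKM did not fully match. Over 8909 genes with more than 200 counts in every library, the length implied by a gene's count and FPKM had a median coefficient of variation of 1.97% between libraries, and it exceeded 5% for 1894 genes. In 51 cases an FPKM above 0 stood beside a count of 0, and in 84 cases a count of at most 2 stood beside an FPKM of 0. The deposited counts may therefore be rounded estimates, or the FPKM values may rest on a length that varied between libraries.

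The comparison of MUCP1-FLAG with LV-NC was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion estimates and TMM scaling. Genes were kept by filterByExpr, with its minimum count of 10, which left 12920 genes. Adjusted p-values were obtained by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. A value after ± beside a log2 fold change is its standard error, computed from the fold change and its F statistic, and CPM values are counts scaled to a common library size by the cpm function of edgeR with TMM factors, given as mean ± SD of 3 libraries. Library totals ran from 17333329 to 23282604 counts, and the common biological coefficient of variation was 0.0521.

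Before the data were examined, 41 gene lists, the rule for named genes, the tests and the alternatives were fixed. The lists covered glutamine and glutamate metabolism, amino acid transporters, the TCA cycle and succinate, mitochondrial carriers, oxidative phosphorylation, other metabolic, stress, signalling, proliferation and epithelial groups, ribosomal proteins, histones, and markers of fibroblasts, blood cells, endothelium and HEK293 packaging cells. Lists with at least 5 tested members, 37 in number, were tested with camera on voom log2 CPM (limma 3.58.1). The inter-gene correlation was preset at 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with the other genes. At a preset correlation its p-value does not measure how far a list as a whole varies between libraries. Camera with an estimated correlation and the rotation test fry, which asks whether the genes of a list move one way and does not compare the list with other genes, were alternatives. With an estimated correlation, the p-value of camera rests on the few residual degrees of freedom of 6 libraries. A list not called there is therefore not shown to be unchanged. KEGG pathways and GO processes were taken from the term columns of the deposited table. Terms with 15 to 500 tested genes were tested with camera in the same way.

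Named genes were the 12 with the largest and the 12 with the most negative log2 fold change among genes with an adjusted p under 0.05, a mean of at least 2 CPM, a gene symbol, and no overlap between the 3 values of one group and the 3 of the other. The rule also added the 4 members with the smallest adjusted p of each list with a called member. From a list without, it added the 2 with the smallest p. These additions had no minimum CPM and no condition on overlap. Some genes that the rule selects are not named in the text or drawn. Further genes were named after their values were seen, where a count was 5 or fewer, where a gene bears on the question of the series or where a pattern was followed up. These were SREBF1, SREBF2, PMVK, FASN, GLUD1, OAT, SUCLA2, SUCLG1, FH, ME2, SDHA, SDHD, SLC25A10, SLC25A15, SLC25A25, SLC2A1, HK2, MAT2A, MTHFD1L, NOP58, AMOTL2, PGK1, BNIP3L, DDIT4, MXI1, PAICS, TGFBI, LTBP2, BAMBI, ABCC3, SRXN1, MYC, RNF43, OAS3, TAP1, KRT19, LOXL2, VIM, CTSL, EPCAM, ITGA1, ITGAV, ITGB5, CD151, CXCL1, TNFAIP3, HBEGF, HSPA5, XBP1, MKI67, MCM6, ABCA1, PLTP, LPCAT3, NR1H3, MYLIP, ZEB1, SNAI1, SNAI2, LCN2, KRT5, IGFBP7, MSX1, TXNIP, CD274, SERPINB5, GPATCH2L, RERE, ELK4, GOLGA3, GAL and HOXC10.

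Alternatives were DESeq2 1.42.0, limma-voom, size factors and upper-quartile factors in place of TMM, no filter and a filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, the replicate number as a block, and each library left out in turn. A correction of each library for gene length and the authors' deposited table were added as alternatives after the data had been seen. The tests were tried on simulated counts for this comparison, with 12892 genes tested, of which 100 were changed by 2-fold and 100 by 1.5-fold. The edgeR test called 92% of the former and 86% of the latter, and 9.64% of its calls were unchanged genes. Of 20 simulated unchanged lists, camera called 0 at the preset correlation and 0 with an estimated correlation, and fry called 2. The simulated genes were drawn independently of each other. This trial therefore could not show calls of lists whose members vary together between libraries. Coordinates are those of GENCODE 29 on GRCh38. No row of the table names MUCP1, so its level is not reported here and the overexpression rests on the labels. Figures were drawn with matplotlib 3.10.9.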

Results

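Transcripts of SW480 colon adenocarcinoma cells were measured by mRNA sequencing in 3 control cultures, LV-NC, and 3 cultures labelled as overexpressing the microprotein MUCP1, MUCP1-FLAG. No gene of the table is named MUCP1, so the overexpression was not verified here. The comparison asks which genes change with raised MUCP1, in particular genes of metabolism and signalling; the title of the series names succinate transport and glutamine metabolism. Total counts were 19130086, 21534908 and 18867369 in the LV-NC libraries and 17333329, 23282604 and 19514699 in the MUCP1-FLAG libraries. Mitochondrially encoded transcripts took 6.10%, 6.61% and 6.16% of counts in LV-NC and 5.91%, 6.24% and 5.92% in MUCP1-FLAG. The first principal component held 42.5% of the variance and parted the groups, at −16.5 to −15.7 for LV-NC and 15.6 or above for MUCP1-FLAG. The second held 17.7% and spread the LV-NC libraries from −17.5 to 18.3. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.991 to 0.993 within groups and 0.987 to 0.989 between them. Within groups the counts of each pair of libraries differed by more than sampling noise, with a chi-square of 2.57 to 8.26 per degree of freedom.

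**Figure D1:**
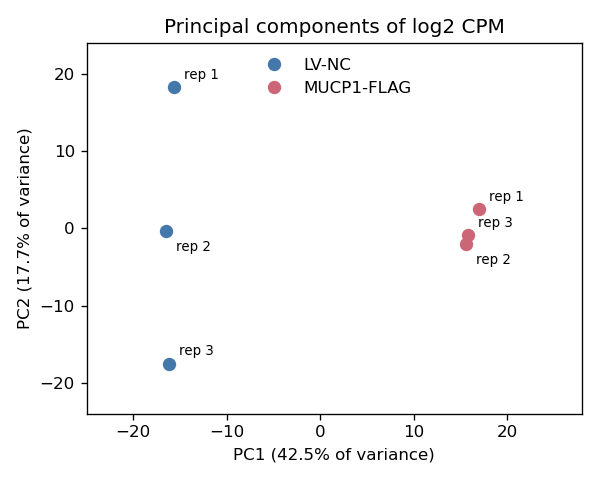
Principal components of log2 CPM, each point 1 of the 6 libraries, with the share of variance of each component on its axis. The LV-NC libraries lie at −16.5 to −15.7 on the first component and the MUCP1-FLAG libraries at 15.6 or above.

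Genes of cholesterol synthesis led the rise in MUCP1-FLAG cells, and the genes with the largest falls included the sterol exporter ABCG1, the chemokine CXCL8 and the EGF receptor ligand AREG. INSIG1, which helps to hold the SREBP factors in the endoplasmic reticulum, rose 5.31-fold, from 30.5 ± 3.29 to 162 ± 22.1 CPM (SD, n = 3 per group). Its log2 fold change was 2.41 ± 0.11, with an edgeR adjusted p of 1.19e-06. HMGCS1, an early enzyme of the mevalonate pathway, rose by 2.08 ± 0.17 on the log2 scale (edgeR adjusted p 0.0014). ACAT2, a cytosolic thiolase, rose by 1.72 ± 0.07, and LIPG, an endothelial-type lipase, by 1.65 ± 0.12. The glycolytic aldolase ALDOC rose by 1.53 ± 0.21. SAA1, an acute-phase apolipoprotein, had a log2 fold change of 1.68 ± 0.12. This value is uncertain because reads may be shared with SAA2, a near-identical copy of the gene. MSMO1, IDI1, MVD and MVK, also among the 12 largest rises, encode enzymes of sterol synthesis. ABCG1, which exports sterols from cells, fell 7.39-fold, from 5.58 ± 1.53 to 0.74 ± 0.15 CPM (log2 fold change −2.89 ± 0.26, edgeR adjusted p 7.67e-08).

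Of the 12 largest falls, CXCL8, the chemokine interleukin-8, had a log2 fold change of −2.06 ± 0.25 (edgeR adjusted p 8.05e-06). The matrix protein gene SPON1 fell with −1.87 ± 0.15 and TRPV6, an epithelial calcium channel, with −1.50 ± 0.11. AREG, a ligand of the EGF receptor, had −1.48 ± 0.16, IL11, a cytokine of the interleukin-6 family, −1.30 ± 0.18, and the immediate early factor EGR2 −1.23 ± 0.22. AP1M2, a subunit of the epithelial clathrin adaptor, had −1.65 ± 0.21, and ITGB6, an epithelial integrin chain, −1.34 ± 0.21. TMC4, the glycosyltransferase GALNT3 and SHF had −1.41 ± 0.19, −1.35 ± 0.21 and −1.34 ± 0.12. On GRCh38, INSIG1 (ENSG00000186480) lies on chromosome 7 at 155297776 to 155310235 (+ strand), MSMO1 (ENSG00000052802) on chromosome 4 at 165327623 to 165343160, ABCG1 (ENSG00000160179) on chromosome 21 at 42199689 to 42297244 and CXCL8 on chromosome 4 at 73740506 to 73743716.

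Over all 12920 tested genes, 1079 were higher and 996 lower in MUCP1-FLAG at an edgeR adjusted p under 0.05, and 47 and 93 of these changed by 2-fold or more. With limma on log2(FPKM + 1) the numbers were 514 higher and 544 lower, with 20 and 13 of 2-fold or more, and on log2(FPKM + 0.1) 516 and 549, with 31 and 62. Most calls were small: 1687 of the 2075 lay within 1.5-fold, and the median absolute log2 fold change of the calls was 0.32. The 3 values of one group lay apart from the 3 of the other for 98.7% of the calls and 33.1% of all tested genes, where chance gives 10%. Without LV-NC replicate 2 the number of higher genes was 671, and without MUCP1-FLAG replicate 3 the numbers were 639 higher and 624 lower. The authors' deposited table had 1521 genes at its adjusted p under 0.05, of which 1497 were among the edgeR calls, 1492 of them in the same direction.

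**Figure D2:**
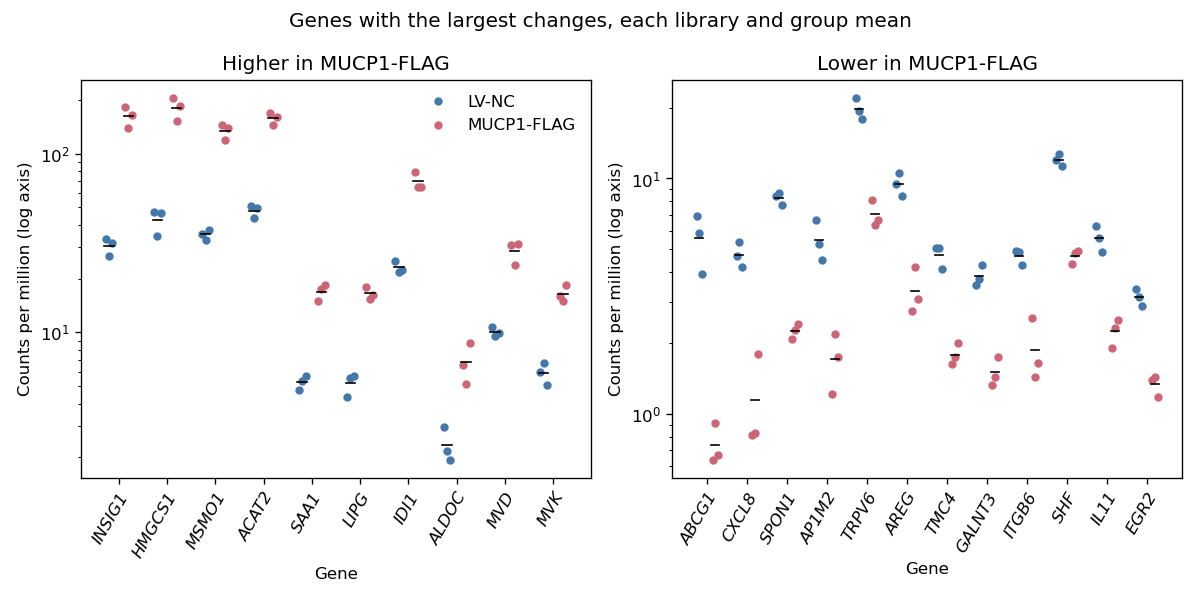
Normalised counts (CPM), on a log axis, of 10 of the 12 genes with the largest and the 12 with the most negative log2 fold change, with 1 point per library, 3 LV-NC and 3 MUCP1-FLAG, and a bar at each group mean. For each gene the 3 values of a group lie apart from the 3 of the other, as the rule of choice required.

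Of the 24 genes of cholesterol synthesis, uptake and its regulation, 23 rose in MUCP1-FLAG cells, also 23 adjusted over the list alone. Their median log2 fold change was 1.11, or 2.16-fold. MSMO1, a sterol C4 demethylating enzyme, rose from 35.3 ± 2.20 to 134 ± 13.5 CPM (log2 fold change 1.93 ± 0.07, edgeR adjusted p 1.15e-12, n = 3 per group). SQLE, squalene epoxidase, rose by 1.44 ± 0.07 and IDI1 by 1.60 ± 0.08. SREBF2, the factor that drives these genes, rose by 0.79 ± 0.05 (edgeR adjusted p 1.71e-09). PMVK was the member that did not pass the test, at 0.02 ± 0.12 (edgeR adjusted p 0.938). The list was called higher by camera (adjusted p 8.66e-46), with an adjusted p of 0.0795 with an estimated correlation.

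Fatty acid synthesis and desaturation moved the same way, with 11 of 15 tested genes higher and 1 lower, also 11 and 1 adjusted over the list alone, and a median log2 fold change of 0.33. The desaturase SCD rose from 327 ± 14.4 to 669 ± 61.9 CPM (1.03 ± 0.06, edgeR adjusted p 8.68e-10, n = 3 per group). FADS1, another desaturase, rose by 0.72 ± 0.05, the acetyl-CoA synthetase ACSS2 by 0.73 ± 0.07 and ACSL1 by 0.35 ± 0.05. FASN, fatty acid synthase, rose by 0.33 ± 0.08 (edgeR adjusted p 0.0165). SREBF1, the factor named for this pathway, was the gene that fell, from 52.6 ± 5.56 to 37.0 ± 1.70 CPM (−0.51 ± 0.07, edgeR adjusted p 5.59e-05). Camera called the list higher (adjusted p 2.0e-09), with an adjusted p of 0.116 with an estimated correlation. The adjusted p of FASN was 0.195 without LV-NC replicate 3 and 0.0507 without MUCP1-FLAG replicate 3.

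Few genes of glutamine and glutamate metabolism were called. Of 29 tested members 3 rose and 2 fell, or 4 and 5 adjusted over the list alone. The 3 and 2 calls lay close to the shares over all 12920 tested genes, of which 1079 were higher and 996 lower. GPT2, a mitochondrial alanine aminotransferase, rose from 55.0 ± 1.56 to 69.1 ± 3.12 CPM (0.33 ± 0.06, edgeR adjusted p 0.00045, n = 3 per group), the glutamate decarboxylase GAD1 by 0.32 ± 0.08 (0.00815) and ornithine aminotransferase, OAT, by 0.15 ± 0.05 (0.0473). CAD, which opens pyrimidine synthesis with glutamine, had −0.24 ± 0.05 (0.00186) and GFPT1, which makes glucosamine phosphate, −0.17 ± 0.05 (0.0224). Glutamate dehydrogenase, GLUD1, had a log2 fold change of 0.10 ± 0.04 (edgeR adjusted p 0.155). The list was not called by camera (adjusted p 0.871, and adjusted p 0.862 with an estimated correlation). Left-out libraries moved several of these calls: GAD1 had an adjusted p of 0.0545 without MUCP1-FLAG replicate 2, GFPT1 of 0.0682, 0.0859 and 0.151 without LV-NC replicate 2, MUCP1-FLAG replicate 2 and MUCP1-FLAG replicate 3, and OAT of 0.0552 to 0.245 when any single library other than LV-NC replicate 3 was left out.

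Of 23 tested amino acid transporters 5 rose, also 5 adjusted over the list alone, where 1 more was lower. These were the glutamate transporter SLC1A3 (0.55 ± 0.13, edgeR adjusted p 0.00517), the cationic carrier SLC7A2 (0.40 ± 0.09), the taurine carrier SLC6A6 (0.25 ± 0.06), and the neutral carriers SLC7A8 (0.17 ± 0.05) and SLC7A5 (0.17 ± 0.05). The list stood just under the threshold in camera (adjusted p 0.0481), with an adjusted p of 0.288 with an estimated correlation. Its adjusted p was 0.0754 without LV-NC replicate 2, 0.0838 without LV-NC replicate 3, 0.0669 without MUCP1-FLAG replicate 1 and 0.0508 without MUCP1-FLAG replicate 3, and the transporter list had 0.0572 with the stricter filter on low counts. Without LV-NC replicate 2 the adjusted p of SLC6A6 was 0.0717, of SLC7A8 0.0654 and of SLC7A5 0.0707; SLC7A8 also had 0.0869 without MUCP1-FLAG replicate 1 and SLC7A5 0.0928 without MUCP1-FLAG replicate 3.

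In the TCA cycle and succinate list 9 of 35 tested genes rose and 1 fell, also 9 and 1 adjusted over the list alone, with a median log2 fold change of 0.06. The risers included the citrate-using enzyme ACLY (0.33 ± 0.05, edgeR adjusted p 7.15e-05), malic enzyme ME1 (0.38 ± 0.06), IDH2 (0.31 ± 0.07) and the pyruvate dehydrogenase subunit PDHA1 (0.22 ± 0.05). ACLY and ME1 are also members of the list of fatty acid synthesis and desaturation, so the calls of these lists are not independent. SUCLA2, a subunit of the enzyme that forms succinate from succinyl-CoA, rose from 50.9 ± 5.52 to 63.4 ± 5.29 CPM (0.32 ± 0.08, edgeR adjusted p 0.00729, n = 3 per group), and fumarase, FH, by 0.23 ± 0.05 (0.00513). The succinate dehydrogenase subunits SDHA and SDHD had 0.11 ± 0.05 (0.150) and 0.02 ± 0.05 (0.813), SUCLG1 0.14 ± 0.05 (0.0932), and the dicarboxylate carrier SLC25A10, which carries succinate, 0.11 ± 0.07 (0.351). ME2, another malic enzyme, was the member that fell (−0.18 ± 0.06, edgeR adjusted p 0.0365). Camera called the list higher (adjusted p 0.00257), with an adjusted p of 0.206 with an estimated correlation. SUCLA2 had an adjusted p of 0.0596 without MUCP1-FLAG replicate 1, SDHA of 0.0389 without LV-NC replicate 1, and ME2 of 0.0755 to 0.148 without LV-NC replicate 2 or any MUCP1-FLAG library.

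Among 40 tested mitochondrial carriers 9 rose and 2 fell, also 9 and 2 adjusted over the list alone. The citrate carrier SLC25A1 rose by 0.63 ± 0.10 (edgeR adjusted p 0.00045), UCP2 by 0.61 ± 0.13, SLC25A29 by 0.40 ± 0.07 and SLC25A23 by 0.34 ± 0.07. SLC25A15, the ornithine carrier, had −0.25 ± 0.06 (0.00965) and SLC25A25, an ATP-Mg carrier, −0.20 ± 0.06 (0.0237). Camera called the carriers higher (adjusted p 0.00989; adjusted p 0.288 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation 12 rose, also 12 adjusted over the list alone, among them ATP5F1C (0.24 ± 0.05), NDUFA12 (0.26 ± 0.06), NDUFS1 (0.19 ± 0.05) and COX7A2 (0.26 ± 0.07), and camera called them higher (adjusted p 5.14e-05; adjusted p 0.5 with an estimated correlation). That call was lost without MUCP1-FLAG replicate 2, with an adjusted p of 0.061. Single members were lost too: NDUFA12 (0.0531) and COX7A2 (0.084) without MUCP1-FLAG replicate 2, COX7A2 (0.0565) without MUCP1-FLAG replicate 3, NDUFS1 without LV-NC replicate 2 (0.0623) or MUCP1-FLAG replicate 1 (0.0727), SLC25A15 without LV-NC replicate 2 (0.0604) or MUCP1-FLAG replicate 2 (0.080), and SLC25A25 without LV-NC replicate 2 or any MUCP1-FLAG library (0.0668 to 0.156).

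Of the 13 mitochondrially encoded mRNAs, MT-CO3 (0.25 ± 0.05, edgeR adjusted p 0.00218) and MT-ATP8 (0.14 ± 0.05, 0.0469) rose, and MT-ND1 (−0.29 ± 0.05, 0.000493) and MT-ND6 (−0.34 ± 0.07, 0.00251) fell; adjusted over the list alone 2 rose and 3 fell, and camera did not call the list of mitochondrially encoded mRNAs (adjusted p 0.252, or 0.0123 without MUCP1-FLAG replicate 2). In glycolysis 10 of 23 genes rose and 2 fell, or 11 and 2 adjusted over the list alone. The glucose carrier SLC2A3 rose by 0.57 ± 0.04 (edgeR adjusted p 5.02e-09), lactate dehydrogenase LDHA by 0.30 ± 0.04 and GAPDH by 0.31 ± 0.05, while the glucose carrier SLC2A1 had −0.15 ± 0.05 (0.0318) and hexokinase HK2 −0.20 ± 0.05 (0.0114). The glycolysis list was called higher (camera adjusted p 2.4e-05; adjusted p 0.354 with an estimated correlation). MT-ATP8 had an adjusted p of 0.0797 to 0.205 without LV-NC replicates 1 or 2 or MUCP1-FLAG replicates 2 or 3, MT-ND6 of 0.0807 without LV-NC replicate 3, HK2 of 0.0659 without MUCP1-FLAG replicate 1, and SLC2A1 of 0.0876 to 0.101 when any single library other than LV-NC replicate 3 was left out.

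Many genes of DNA replication and of mitosis rose by small amounts. In the list of G1/S and DNA replication genes 23 of 36 rose, or 30 adjusted over the list alone, with a median log2 fold change of 0.23. With limma on log2(FPKM + 1) or log2(FPKM + 0.1) 15 of the G1/S members were higher, and without LV-NC replicate 2 the number was 16. The ribonucleotide reductase subunit RRM2 rose from 455 ± 13 to 693 ± 22.8 CPM (0.61 ± 0.04, edgeR adjusted p 3.87e-09, n = 3 per group), thymidylate synthase TYMS by 0.63 ± 0.05, the sliding clamp PCNA by 0.36 ± 0.05 and the helicase subunit MCM6 by 0.27 ± 0.04. In the list of G2/M and mitosis genes 20 of 33 rose, or 27 adjusted over the list alone, with a median of 0.20. KIF20A rose by 0.46 ± 0.07, CDCA3 by 0.51 ± 0.08, TOP2A by 0.35 ± 0.05, FOXM1 by 0.29 ± 0.05 and MKI67, which encodes the proliferation marker Ki-67, by 0.20 ± 0.05 (edgeR adjusted p 0.00467). Camera called the G1/S list higher (adjusted p 4.3e-18) and the G2/M list too (adjusted p 3.0e-12), each with an adjusted p of 0.0795 with an estimated correlation. Without LV-NC replicate 2 the adjusted p of MKI67 was 0.0516.

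Of 11 tested histone genes of the replication-dependent clusters 3 fell, also 3 adjusted over the list alone, with a median log2 fold change of −0.54. H2AC6 fell from 22.8 ± 3.31 to 10.7 ± 0.52 CPM (−1.10 ± 0.10, edgeR adjusted p 1.78e-07, n = 3 per group), H2BC5 had −0.88 ± 0.13 and H2BC21 −0.59 ± 0.10. Most transcripts of this family lack the poly(A) tail that mRNA kits select, and its members share sequence, so these values are uncertain. Camera called the list lower (adjusted p 0.0015), with an adjusted p of 0.112 with an estimated correlation and of 0.153 without the low-count filter.

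Many genes that respond to MAPK signalling fell. Of 33 tested immediate early and MAPK feedback genes 19 were lower, or 22 adjusted over the list alone, with a median log2 fold change of −0.20. The early factor EGR1 fell from 372 ± 24.4 to 239 ± 11.4 CPM (−0.64 ± 0.05, edgeR adjusted p 1.98e-08, n = 3 per group). PHLDA1 had −0.65 ± 0.05, the ERK phosphatase gene DUSP5 −0.56 ± 0.05, and the EGF receptor ligands EREG and HBEGF −1.06 ± 0.10 and −0.76 ± 0.07, beside AREG above. MYC was among the lower genes (−0.18 ± 0.04, edgeR adjusted p 0.0071). The list was called lower (camera adjusted p 3.13e-13), with an adjusted p of 0.152 with an estimated correlation. MYC had an adjusted p of 0.0747 without LV-NC replicate 2 and 0.0519 without MUCP1-FLAG replicate 3.

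Of 18 tested NF-kB and TNF response genes 11 fell, or 14 adjusted over the list alone, with a median log2 fold change of −0.38. Beside CXCL8, the chemokine CXCL1 had −1.56 ± 0.27, CSF2, which encodes GM-CSF, −0.80 ± 0.11, TNFAIP3, a feedback inhibitor of NF-kB, −0.65 ± 0.13, the adhesion molecule ICAM1 −0.46 ± 0.05 (edgeR adjusted p 3.97e-06) and the cytokine LIF −0.34 ± 0.05. CXCL1 was low, at 2.42 ± 0.07 CPM in LV-NC and 0.81 ± 0.17 CPM in MUCP1-FLAG. Camera called the NF-kB and TNF list lower (adjusted p 2.0e-09, or 0.0795 with an estimated correlation). Of 14 MHC class I presentation genes 7 fell, and adjusted over the list alone 7 were lower and 2 higher. HLA-B fell from 199 ± 13.6 to 132 ± 6.81 CPM (−0.59 ± 0.06, edgeR adjusted p 1.78e-07, n = 3 per group), HLA-F had −0.59 ± 0.12 and HLA-E −0.21 ± 0.05; reads can be shared within this family, so the size for each gene is uncertain. The list was called lower (camera adjusted p 0.0044; adjusted p 0.369 with an estimated correlation). In the interferon response list 2 of 30 genes rose and 4 fell, or 2 and 5 adjusted over the list alone, and camera did not call it (adjusted p 0.113, or 0.0357 without MUCP1-FLAG replicate 3). IFI27 (0.92 ± 0.12) and OAS3 (0.25 ± 0.06) rose, and OASL (−1.94 ± 0.39), MX2 (−0.61 ± 0.12), IFIH1 (−0.51 ± 0.09) and TAP1 (−0.23 ± 0.07) fell. OASL was low, at 1.63 ± 0.33 CPM in LV-NC and 0.43 ± 0.25 CPM in MUCP1-FLAG, so its fold rests on few counts. TAP1 had an adjusted p of 0.0638 to 0.145 without LV-NC replicates 1 or 2 or MUCP1-FLAG replicates 1 or 2.

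Part of the epithelial adhesion genes fell. Of 28 tested junction and keratin genes 13 were lower and 1 higher, or 14 and 3 adjusted over the list alone, with a median log2 fold change of −0.26. The claudin CLDN7 fell from 69.4 ± 2.33 to 30.5 ± 1.96 CPM (−1.18 ± 0.07, edgeR adjusted p 4.1e-11, n = 3 per group) and CDH1, which encodes E-cadherin, from 31.2 ± 0.65 to 14.9 ± 0.24 CPM (−1.06 ± 0.08, edgeR adjusted p 3.26e-09). ESRP1, a splicing factor of epithelial cells, had −0.89 ± 0.07, KRT80 −0.39 ± 0.05 and EPCAM −0.33 ± 0.05. KRT19 was the member that rose (0.17 ± 0.05, edgeR adjusted p 0.0322). Camera called the list lower (adjusted p 5.47e-07), with an adjusted p of 0.0795 with an estimated correlation. KRT19 had an adjusted p of 0.0533 to 0.189 when any single library other than LV-NC replicate 1 was left out.

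Among 22 tested integrin and laminin genes 9 fell and 4 rose, or 9 and 5 adjusted over the list alone. LAMA3 (−1.05 ± 0.05, edgeR adjusted p 1.49e-11) and LAMB3 (−0.41 ± 0.06), chains of laminin-332, fell with ITGB6 and with FERMT1 (−0.63 ± 0.05), an integrin activator of epithelia. ITGA1 (0.31 ± 0.06), ITGAV (0.26 ± 0.07), CD151 (0.23 ± 0.05) and ITGB5 (0.21 ± 0.05) rose. Camera called this list lower (adjusted p 0.00989; adjusted p 0.369 with an estimated correlation). Of 9 tested genes of colonic differentiation 4 fell, or 5 adjusted over the list alone: MUC1 (−0.87 ± 0.16, edgeR adjusted p 0.000626), CEACAM1 (−0.75 ± 0.14), KLF4 (−0.55 ± 0.08) and VIL1 (−0.40 ± 0.10). Camera called it lower (adjusted p 0.0044), with an adjusted p of 0.181 with an estimated correlation and of 0.0529 without the low-count filter. The mesenchymal list went both ways, with 4 of 24 genes higher and 8 lower, also 4 and 8 adjusted over the list alone, and was not called (camera adjusted p 0.110). FN1 (0.65 ± 0.07), S100A4 (0.40 ± 0.05), LOXL2 (0.35 ± 0.08) and VIM (0.17 ± 0.04) rose, while PLAU (−1.14 ± 0.08, edgeR adjusted p 2.43e-09) and COL6A1 (−0.54 ± 0.06) fell. ITGAV had an adjusted p of 0.0543, 0.0886, 0.109 and 0.0812 without LV-NC replicate 1, LV-NC replicate 2, MUCP1-FLAG replicate 1 and MUCP1-FLAG replicate 3, and VIM of 0.0577 and 0.0697 without MUCP1-FLAG replicates 2 and 3.

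**Figure D3:**
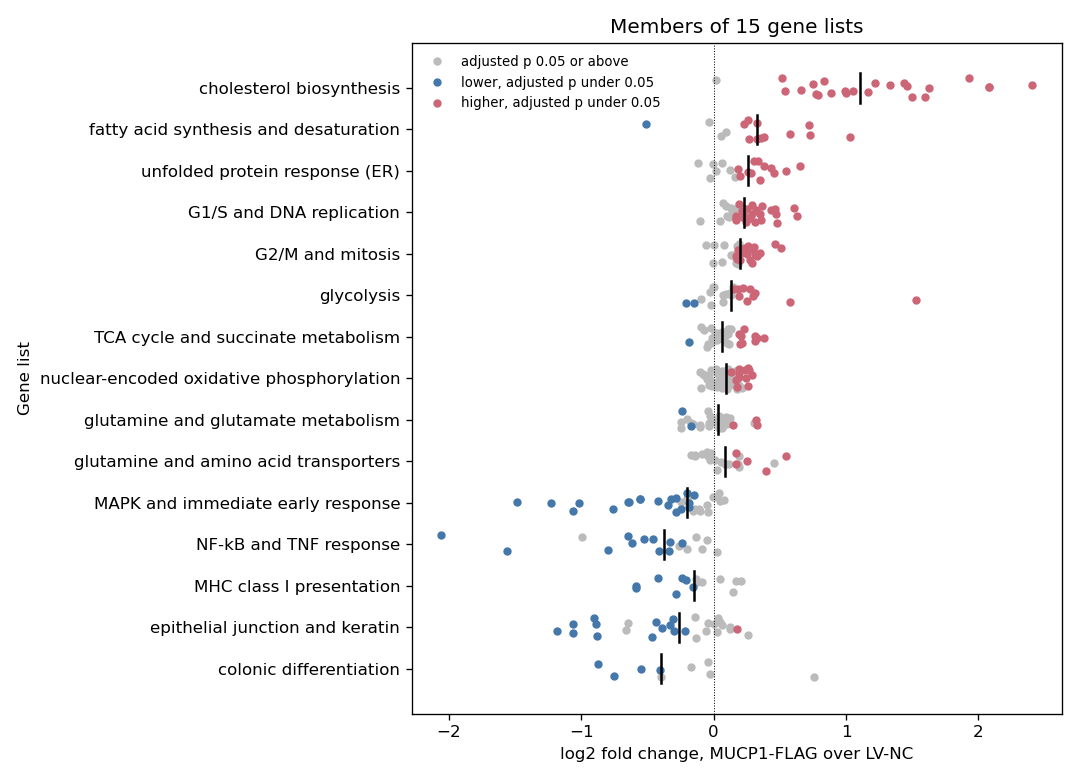
Log2 fold change of MUCP1-FLAG over LV-NC for the tested members of 15 gene lists, each point a gene, coloured by its direction where the edgeR adjusted p was under 0.05 and grey otherwise, with a black bar at the median of the list. The median is 1.11 for cholesterol biosynthesis and −0.40 for colonic differentiation, and glutamine and glutamate metabolism has members on both sides of 0.

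Several endoplasmic reticulum chaperones rose in MUCP1-FLAG cells. Of 19 genes of the unfolded protein response 12 rose, or 13 adjusted over the list alone, with a median log2 fold change of 0.26. Calreticulin, CALR, rose from 501 ± 19.2 to 786 ± 13.3 CPM (0.65 ± 0.04, edgeR adjusted p 1.34e-09, n = 3 per group), MANF by 0.45 ± 0.06, HERPUD1 by 0.43 ± 0.05, PDIA6 by 0.35 ± 0.04, XBP1 by 0.33 ± 0.05 and HSPA5, the chaperone BiP, by 0.20 ± 0.04. Camera called the list higher (adjusted p 1.26e-09; adjusted p 0.0795 with an estimated correlation). In the ATF4 and integrated stress response list 7 of 31 genes rose, and adjusted over the list alone 7 were higher and 1 lower, with NUPR1 at 0.85 ± 0.21, ATF4 at 0.22 ± 0.04 and STC2 at 0.24 ± 0.05. Camera did not call it (adjusted p 0.0740), but did without LV-NC replicate 1 (0.0477), without LV-NC replicate 2 (0.0151) or without the low-count filter (0.0436), and NUPR1 had an adjusted p of 0.0835 without MUCP1-FLAG replicate 2. OMA1, a mitochondrial protease, fell (−0.62 ± 0.12, edgeR adjusted p 0.000888), the member of 13 mitochondrial chaperones and proteases that was called, also 1 adjusted over the list alone (camera adjusted p 0.936; the median lay above 0 and the mean below).

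Targets of Wnt signalling rose in part, 7 of 21 with 2 lower, or 8 and 2 adjusted over the list alone. The feedback inhibitors NOTUM (0.77 ± 0.10, edgeR adjusted p 9.39e-06) and AXIN2 (0.27 ± 0.04) rose with SP5 (0.47 ± 0.07) and LEF1 (0.29 ± 0.06), and MYC and RNF43 (−0.18 ± 0.06, 0.0455) were lower. The list was called higher (camera adjusted p 0.00532; adjusted p 0.116 with an estimated correlation). Of 17 NRF2 targets 6 rose and 2 fell, also 6 and 2 adjusted over the list alone: the pentose phosphate enzyme PGD (0.42 ± 0.05) and NQO1 (0.25 ± 0.05) were among the risers, and ABCC3 (−0.27 ± 0.05) and SRXN1 (−0.18 ± 0.05) fell. The NRF2 list was called higher (camera adjusted p 0.0471; adjusted p 0.369 with an estimated correlation), but not without LV-NC replicate 3 (0.0959), MUCP1-FLAG replicate 1 (0.0502) or MUCP1-FLAG replicate 2 (0.0956), nor with the stricter filter on low counts (0.0558). The adjusted p of RNF43 was 0.073 to 0.203 when LV-NC replicate 2 or any MUCP1-FLAG library was left out, and SRXN1 had 0.0903, 0.0557 and 0.0504 without LV-NC replicate 2, MUCP1-FLAG replicate 1 and MUCP1-FLAG replicate 3.

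In fatty acid oxidation 7 of 22 genes rose and 1 fell, or 8 and 1 adjusted over the list alone. The electron transfer flavoprotein subunits ETFA (0.36 ± 0.06, edgeR adjusted p 0.000183) and ETFB (0.36 ± 0.08) and the dehydrogenase HADH (0.35 ± 0.07) rose, and PPARA fell (−0.32 ± 0.08, 0.00846; by limma on log2(FPKM + 1) it had 0.18 ± 0.15, adjusted p 0.526). Camera called the list higher (adjusted p 0.0240; adjusted p 0.416 with an estimated correlation), but not without LV-NC replicate 3 (0.0959) or MUCP1-FLAG replicate 2 (0.061), where PPARA also had 0.061. Of 25 lysosomal and autophagy genes 6 rose and 1 fell, or 9 and 1 adjusted over the list alone, with ATP6V0D1 at 0.28 ± 0.06 and CTSL at −0.17 ± 0.05. That list was called higher (camera adjusted p 0.0106; adjusted p 0.369 with an estimated correlation; 0.083 without LV-NC replicate 3), and CTSL had an adjusted p of 0.0627 to 0.190 without LV-NC replicate 2 or any MUCP1-FLAG library.

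In serine and one-carbon metabolism 6 of 23 genes rose and 2 fell, also 6 and 2 adjusted over the list alone. SHMT1 rose by 0.30 ± 0.07 (edgeR adjusted p 0.00299) and GCSH by 0.27 ± 0.07 beside TYMS, while MAT2A had −0.16 ± 0.04 (0.0132) and MTHFD1L −0.17 ± 0.06 (0.0385). The list was called higher (camera adjusted p 0.0225; adjusted p 0.288 with an estimated correlation; 0.0838 without LV-NC replicate 3). Purine and pyrimidine synthesis had 3 of 21 genes higher, TYMS, DUT (0.42 ± 0.06) and PAICS (0.13 ± 0.04), and 2 lower, CAD and IMPDH2 (−0.16 ± 0.05), with the same numbers adjusted over the list alone, and was not called (camera adjusted p 0.0608). The list of purine and pyrimidine synthesis was called without LV-NC replicate 1 (0.027), without MUCP1-FLAG replicate 3 (0.0444) or without the low-count filter (0.0301). MAT2A, MTHFD1L, PAICS and IMPDH2 each lost the call without LV-NC replicate 2, with adjusted p of 0.0855, 0.103, 0.141 and 0.102, and without MUCP1-FLAG replicate 1 or 3 (0.057 to 0.177). GCSH lost it without LV-NC replicate 2 (0.0513) or MUCP1-FLAG replicate 3 (0.057).

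Lists that camera did not call held single genes past the test. Over all 12920 tested genes 1079 were higher and 996 lower, so a few calls in a list are common. In the hypoxia list 5 of 26 genes rose, LDHA, STC2, PGK1 (0.16 ± 0.04), BNIP3L (0.19 ± 0.06) and DDIT4 (0.22 ± 0.07), and 4 fell, CA12 (−1.12 ± 0.30, edgeR adjusted p 0.012), EGLN1 (−0.27 ± 0.06), MXI1 (−0.32 ± 0.09) and SLC2A1 (camera adjusted p 0.519; 6 and 6 adjusted over the list alone). Of 30 MYC targets 3 rose, LDHA, ODC1 (0.20 ± 0.04) and CDK4 (0.17 ± 0.05), and 2 fell, CAD and NOP58 (−0.14 ± 0.05), also 3 and 2 adjusted over the list alone (camera adjusted p 0.459). Of 22 p53 targets DDB2 rose (0.36 ± 0.08) and TNFRSF10B (−0.31 ± 0.05), PLK3 (−0.38 ± 0.10) and AEN (−0.20 ± 0.05) fell, also 1 and 3 adjusted over the list alone (camera adjusted p 0.442). In the TGF-beta list of 20 genes ID2 (0.76 ± 0.05, edgeR adjusted p 2.9e-09), TGFBI (0.24 ± 0.05), LTBP2 (0.26 ± 0.06) and BAMBI (0.21 ± 0.06) rose and 3 fell, among them THBS1 (−0.39 ± 0.07) and PMEPA1 (−0.32 ± 0.05), or 4 and 5 adjusted over the list alone (camera adjusted p 0.323). The YAP list had 6 of 20 genes higher, with ANKRD1 at 0.39 ± 0.05 and CRIM1 at 0.37 ± 0.05, and 3 lower, F3 (−0.69 ± 0.10), NT5E (−0.48 ± 0.07) and AMOTL2 (−0.21 ± 0.05), also 6 and 3 adjusted over the list alone (camera adjusted p 0.442). CA12 was low, at 1.61 ± 0.11 CPM in LV-NC and 0.73 ± 0.13 CPM in MUCP1-FLAG. In the hypoxia and YAP lists the median and the test pointed up and the mean down. Some of these calls were lost with a library left out, which also lowers the power of the test. The edgeR adjusted p reached 0.0574 for CA12 and 0.143 for BNIP3L without MUCP1-FLAG replicate 1. It reached 0.0885 for PGK1, 0.0998 for CDK4 and 0.158 for NOP58 without MUCP1-FLAG replicate 2. Without MUCP1-FLAG replicate 3 it reached 0.178 for DDIT4, 0.0858 for PLK3 and 0.0955 for BAMBI. Without LV-NC replicate 2 it reached 0.123 for MXI1 and 0.108 for AEN.

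Ribosomal and heat shock genes moved little. Of 66 cytosolic ribosomal proteins RPS19 (−0.15 ± 0.05) and RPS12 (−0.16 ± 0.05) fell, and 0 were called adjusted over the list alone (camera adjusted p 0.201, with calls of the cytosolic ribosomal proteins without LV-NC replicate 3 at 0.00212 and MUCP1-FLAG replicate 2 at 3.81e-05). Of 58 mitochondrial ribosomal proteins MRPS6 (0.51 ± 0.05, edgeR adjusted p 6.02e-08), MRPL37 (0.19 ± 0.05) and MRPL23 (0.24 ± 0.08) rose, with 1 call adjusted over the list alone (camera adjusted p 0.257). FKBP4 (−0.16 ± 0.05) was the called gene of 16 of the heat shock response, with 0 adjusted over the list alone (camera adjusted p 0.312). The adjusted p reached 0.163 for RPS19 and 0.131 for FKBP4 without LV-NC replicate 2, 0.213 for RPS12 without MUCP1-FLAG replicate 1, 0.152 for MRPL23 without MUCP1-FLAG replicate 2 and 0.0782 for MRPL37 without MUCP1-FLAG replicate 3. Of the 37 tested lists camera called 15 higher and 7 lower at the preset correlation, and 0 with an estimated correlation; fry called 22, of which 19 were among the camera calls. The camera calls that fry did not make were oxidative phosphorylation (adjusted p 0.206), fatty acid oxidation (0.0525) and lysosome and autophagy (0.0516), and fry alone called p53 targets (0.0195), the mesenchymal list (0.016) and purine and pyrimidine synthesis (0.0271).

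Terms of the deposited annotation gave 26 KEGG pathways higher and 8 lower of 299, and 58 GO processes higher and 7 lower of 1501, by camera with the preset correlation; 0 of either kind were called with an estimated correlation. Steroid biosynthesis led the KEGG pathways, with 15 of 18 genes higher (adjusted p 5.88e-21; adjusted p 0.480 with an estimated correlation), followed by DNA replication with 17 of 38 higher (adjusted p 1.19e-08; 0.480 likewise). In the proteasome pathway 13 of 43 genes were higher (adjusted p 3.86e-06; adjusted p 0.766 with an estimated correlation). Among the lower pathways, 27 of 70 cell adhesion molecule genes fell and 3 rose (adjusted p 7.2e-06, or 0.517 with an estimated correlation). In complement and coagulation 11 of 33 genes fell and 2 rose (adjusted p 0.00024, or 0.480 likewise). Some GO processes with names close to lists above were called the other way, and which genes they share was not analysed. TAP-dependent presentation by MHC class I had 17 of 65 genes higher and 7 lower (camera adjusted p 0.00826). NIK/NF-kappaB signalling had 12 of 61 genes higher and 3 lower (camera adjusted p 0.0152). Both were called higher, each with an adjusted p of 0.855 with an estimated correlation. NIK/NF-kappaB signalling had the same median log2 fold change, 0.0959, as anaphase-promoting complex-dependent catabolism. TAP-dependent presentation had the same median, 0.103, as regulation of hematopoietic stem cell differentiation. Such terms may share genes, so a conflict with the falls in the lists above was not shown.

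Most markers of other cell types were under 2 CPM. Of 12 fibroblast markers 11 had a mean under 2 CPM in both groups and 6 had no count in any library; ACTA2, the exception, rose from 3.62 ± 0.52 to 5.22 ± 0.59 CPM (0.53 ± 0.16, edgeR adjusted p 0.0318, n = 3 per group). Of 14 lymphoid and myeloid markers 13 were under 2 CPM, and CD68, a lysosomal protein that is not restricted to macrophages, fell from 12.6 ± 0.45 to 8.21 ± 1.07 CPM (−0.62 ± 0.11, edgeR adjusted p 0.000554). Of 9 endothelial markers 7 were under 2 CPM, and VWF (0.09 ± 0.23) and ROBO4 (−0.36 ± 0.16) did not pass the test, ROBO4 with an adjusted p of 0.147, or 0.0386 without LV-NC replicate 3. Of 11 markers of HEK293 packaging cells 8 were under 2 CPM and 3 were well above. PAX8 fell from 33.1 ± 1.18 to 26.9 ± 1.96 CPM (−0.31 ± 0.08, edgeR adjusted p 0.00716), while GAL, at 37.9 ± 3.23 CPM in LV-NC, had a log2 fold change of −0.03 ± 0.08 (0.839) and HOXC10, at 14.7 ± 0.29 CPM, of −0.11 ± 0.10 (0.475). Adjusted over the list alone the fibroblast list had 1 higher gene, the lymphoid and myeloid and the HEK293 list 1 lower gene each, and these lists had too few tested members for camera. ACTA2 had an adjusted p of 0.0836, 0.0925, 0.0595 and 0.165 without LV-NC replicate 2, LV-NC replicate 3, MUCP1-FLAG replicate 2 and MUCP1-FLAG replicate 3, and PAX8 of 0.0713 without MUCP1-FLAG replicate 2.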

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

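The gene length correction and the authors' deposited table were alternatives chosen after the data had been seen. Numbers of higher, lower, 2-fold higher and 2-fold lower genes stayed within 1.5 times those reported with DESeq2 (890, 744, 37 and 70), size factors, upper-quartile factors (926, 1127, 47 and 99), both other filters, limma-voom, the length correction (1228, 1081, 48 and 94) and the authors' deposited table (824, 697, 36 and 76). They fell to 514, 544, 20 and 13 with log2(FPKM + 1), to 516, 549, 31 and 62 with log2(FPKM + 0.1) and to 380, 406, 20 and 13 with log2(FPKM + 1) over all genes; the pseudocount shrinks folds of low genes by construction, and the cause of the rest was not tested. With 1 library left out the ranges were 639 to 1323, 624 to 1213, 40 to 53 and 83 to 106, with fewer libraries by construction. The upper ends, above the counts with all libraries, came without LV-NC replicate 3, and the cause of that rise was not tested. Same-numbered libraries of the 2 groups had deviations with r of 0.04, 0.05 and 0.00 across genes, so the numbers were not read as pairs, and LV-NC replicate 3 did not correlate best with its own number; the replicate block gave 1005, 954, 45 and 91 genes, 22 called lists and p-values of 0.874 for glutamine and 0.00295 for the TCA cycle.

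The 22 called lists lost their call with an estimated correlation, where 6 libraries leave the test few degrees of freedom. That loss alone does not show that the lists are unchanged. Fry kept 19, size factors 22, the stricter filter 20, no filter 20 and left-out libraries 17 to 22. The TCA cycle had an adjusted p of 0.206 with an estimated correlation and 0.00107 to 0.0098 with 1 library left out; glutamine had 0.768 to 0.977 and pointed lower without MUCP1-FLAG replicate 2 (0.977). Uncalled lists changed sign: mitochondrial chaperones without a filter (0.938) and without LV-NC replicate 1 (0.979), LV-NC replicate 2 (0.895), MUCP1-FLAG replicate 1 (0.886) or MUCP1-FLAG replicate 3 (0.981), with 0.631 the lowest, and cytosolic ribosomal proteins without LV-NC replicate 2 (0.961) or MUCP1-FLAG replicate 1 (0.721), with 3.81e-05 the lowest. Of 224 genes chosen by the rule or named after their values were seen, 214 kept side and sign with DESeq2, 224 with size factors, 220 with upper-quartile factors, 165 with log2(FPKM + 1), 166 with log2(FPKM + 0.1), 140 with log2(FPKM + 1) over all genes, 217 with the replicate block, 217 with the length correction, 201 in the authors' deposited table, and 181 to 212 with 1 library left out. Signs turned in FPKM at + 1, at + 0.1 and over all genes, and in the authors' deposited table, for PPARA (0.18, 0.21, 0.18 and 0.23), ELK4 (0.036, 0.038, 0.036 and 0.054), GOLGA3 (0.022, 0.023, 0.022 and 0.036), GPATCH2L (0.032, 0.034, 0.032 and 0.029), RERE (−0.023, −0.024, −0.023 and −0.036) and ZEB1 (−0.0043, −0.0042, −0.0043 and −0.010). Genes near 0 also turned: GAL without LV-NC replicate 1 (0.036) or MUCP1-FLAG replicate 1 (0.039, the range starting at −0.096), ZEB1 without LV-NC replicate 1 (−0.015), VWF without LV-NC replicate 2 (−0.018) or MUCP1-FLAG replicate 1 (−0.17, the range reaching 0.29), and PMVK without LV-NC replicate 2 (−0.10, the range reaching 0.15) or MUCP1-FLAG replicate 2 (−0.05), with the length correction (−0.0089) and in the authors' deposited table (−0.0071). The cause of these turns was not tested. At 17333329 to 23282604 counts per library, 12920 of 20289 genes passed the filter, and the rest were too low to be tested.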

Other observations

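The test of a mesenchymal mixture below was chosen after its result had been seen, and the correction for gene length and the comparison with the authors' deposited table after the data had been seen. Other genes with large changes lay outside the fixed lists and were picked after their values were seen. The basal keratin KRT5 rose from 479 ± 14.1 to 887 ± 19.1 CPM (0.89 ± 0.04, edgeR adjusted p 1.06e-11, n = 3 per group), IGFBP7, a secreted binding protein, by 1.18 ± 0.06 and the homeobox gene MSX1 by 1.09 ± 0.07. SERPINB5 fell with −1.19 ± 0.15, the glucose-responsive gene TXNIP with −0.92 ± 0.10, LCN2 with −0.85 ± 0.15 (edgeR adjusted p 0.0241) and CD274, which encodes PD-L1, with −0.82 ± 0.19. The call of LCN2 was lost without LV-NC replicate 1 (0.056), LV-NC replicate 3 (0.0807) or MUCP1-FLAG replicate 3 (0.0614).

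For 5 genes called both by edgeR and in the authors' deposited table, whose test is not given in the sources used here, the counts and the mean FPKM values gave opposite signs: GPATCH2L, PPARA, ELK4, GOLGA3 and RERE. By limma on log2(FPKM + 1) these genes did not pass the threshold, with adjusted p of 0.526 to 0.941 and values under 1.5 standard errors from 0, such as 0.03 ± 0.08 for GPATCH2L, so opposite changes were not shown. GPATCH2L had a log2 fold change of −0.34 ± 0.07 by edgeR and 0.029 in the authors' deposited table. The length implied by its count and FPKM was 4564 ± 145 bases in LV-NC and 3501 ± 217 bases in MUCP1-FLAG (SD, n = 3 per group), and for PPARA 7075 ± 800 and 4978 ± 1524 bases. Without MUCP1-FLAG replicate 3 the adjusted p of ELK4 was 0.143, of RERE 0.111 and of GOLGA3 0.0734, and without MUCP1-FLAG replicate 2 that of PPARA was 0.061. No explanation was tested.

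The rise of 23 of 24 sterol synthesis genes came with the fall of the exporter gene ABCG1. A trend with gene length is argued against as the whole cause, since 23 members stayed higher after the length correction. That correction changed the call of 406 other genes. The trend was weak, with a Spearman's rho of −0.10 between log2 fold change and implied length across genes. This outcome of the correction was therefore likely beforehand. A single library is argued against too, since at least 22 members were higher whichever was left out. A candidate explanation is that the MUCP1-FLAG cells sensed less sterol, which lowers targets of the oxysterol receptor LXR. Of 9 LXR targets not seen before, ABCA1 (−2.43 ± 0.44), PLTP (−0.42 ± 0.07), NR1H3 (−0.46 ± 0.14) and LPCAT3 (−0.21 ± 0.07) were lower by edgeR. The other 5 were not called, and the median log2 fold change over the 9 was −0.20. The fall of the targets ABCG1 and MYLIP (−1.16 ± 0.16) had been seen before. These targets are a chosen set that left out genes of the fatty acid list. There SREBF1 fell (−0.51 ± 0.07), while SCD (1.03 ± 0.06) and FASN (0.33 ± 0.08) rose. The fall thus covers the chosen targets and not every gene that LXR may drive. The calls of NR1H3 and LPCAT3 were lost with DESeq2 (0.107 and 0.0744) and reached 0.133 and 0.169 without MUCP1-FLAG replicate 3, and a difference in culture density, in how far serum in the medium was used up or in the making of the 2 lines, none of which was analysed here, stays open as the origin of such a state.

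Of the junction and keratin genes 13 fell. Gene length is argued against as the whole cause, since 14 members were lower after its correction. The weak trend with length made this outcome likely beforehand too. Whether the MUCP1-FLAG cultures held more cells of a mesenchymal kind stays open, since the mesenchymal list went both ways, with 8 called members lower and 4 higher. More mRNA of the repressors of epithelial genes was not detected, but the errors of SNAI1 and ZEB1 leave a rise open, which the bound set beforehand, a count of calls, did not allow for: 0 of 3 tested were higher by edgeR, at an adjusted or an unadjusted p under 0.05, and 0 by DESeq2, with SNAI1 at 0.35 ± 0.26 (edgeR adjusted p 0.400), ZEB1 at 0.09 ± 0.10 (0.583; 0.0487 without LV-NC replicate 3) and SNAI2 lower at −0.28 ± 0.09 (0.0414, lost with DESeq2 at 0.129 and without MUCP1-FLAG replicate 3 at 0.170). Protein levels and the difference between the 2 lines before MUCP1 was raised were not analysed here, so a biological origin stays a hypothesis.

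The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The labelled split was 1 of the 10 with as many calls, 2075 against at most 0 in the other 9 by edgeR (84 to 545 genes there had an unadjusted p under 0.05, and DESeq2 called at most 2), and the same 1 of the 10 for 2-fold calls, 140 against at most 0. For gene lists it was also 1 of 10, 22 against 7 to 18. Every other split puts libraries of both groups on each side and keeps a part of the difference between the groups. That difference also adds to the spread within each side, so the 0 gene calls there do not measure noise alone. The sterol list was called in 9 of 9 other splits, with a smallest camera adjusted p of 2.74e-09 against 8.66e-46. Cytosolic ribosomal proteins, not called between the groups, were called in 7 of the 9 other splits and oxidative phosphorylation in 7, with smallest adjusted p of 2.89e-26 and 1.21e-17, both below their values between the groups of 0.201 and 5.14e-05. At the preset correlation camera may thus call lists whose members vary together between libraries. Of the 22 called lists, 16 had an adjusted p below that of every other split. Besides oxidative phosphorylation, the rest had a smaller camera adjusted p in another split than between the groups. These were glycolysis (1.71e-05 against 2.4e-05), mitochondrial carriers (0.0065 against 0.00989) and fatty acid oxidation (0.00542 against 0.0240). MHC class I presentation (0.00107 against 0.0044) and lysosome and autophagy (0.0038 against 0.0106) were the others.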
